A study of Drosophila melanogaster with 2 samples.

How the data were processed

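Hr96 fused to eGFP was measured by ChIP-seq with an anti-GFP antibody in whole adult females, in 2 biological replicates (numbered 1 and 3) that the labels place in 1 group. Each deposited peak list has a signal value per peak, the strength the authors' peak caller gave it against a control, and the −log10 of a q-value, both identified by the column order of the narrowPeak format. The signal scale differs between libraries, so signals were tested for a difference only between genes within the IDR list, and otherwise used to rank, correlate and describe peaks. Per the deposited text lists, each replicate's peaks and background regions were called from its own alignments and 1 control file shared by both replicates, the pooled list came from both replicates' alignments, and the IDR list was derived from these. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The control libraries were not analysed here. The labels name Hr96 as the antibody and elsewhere describe an antibody to GFP, and the latter description is followed here. The labels call the samples biological replicates. With 2 of them, tests are across peaks or genes and measure no spread between animals.

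Peaks were ranked by signal, and peaks of 2 lists matched where their summits lay within 100 bp. Gene positions came from the Ensembl annotation of the BDGP6 (dm6) assembly and sequence from the RefSeq copy of that assembly. The dm3 lists were compared by counts, signals and overlap with each other, with no conversion of coordinates, and dm3 arm lengths were approximated by the furthest peak. A gene was bound where an IDR summit lay within 500 bp of any of its TSSs, and the background was all 13945 protein-coding genes on the 6 main arms. Features were assigned by priority (promoter, 5' untranslated, 3' untranslated, coding, other exon, intron, intergenic). Null sets were 10000 circular shifts, 10000 sets of random positions matched for arm, and 10000 rotations of gene labels along the genome. Gene lists were compared by two-sided Fisher's exact tests and motifs by two-sided exact sign tests of each summit window of 201 bp against 1 flank 1000 bp away, its side drawn at random. Both were adjusted by Benjamini-Hochberg over 16 lists and 17 motifs, with a threshold of 0.05. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, and a count of 0 was given the limit that 3 counts allow. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

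The gene lists, motifs, tests, named-gene rule and most alternatives were fixed before the data were examined. The lists are sterol handling, triacylglycerol, xenobiotic, nuclear receptor, nutrient signalling, oogenesis, ribosomal protein, proteasome, heat shock, Polycomb control, testis, neuron, muscle, gut, fat body and circadian genes. The Polycomb control list holds homeobox genes and other developmental genes. Named genes are those with the TSS nearest to each of the 10 strongest IDR peaks, up to 4 members per list with the strongest peak within 500 bp of a TSS, and Hr96, mag and Npc1b whatever their value. The lipase gene bmm was named after its value was seen. Of 499 list entries, 497 matched a gene, 10 of them by a synonym. After a first run of the list tests had been seen, 5 names that had stayed unmatched (magro, Tor, nos, rye and Dl) were resolved by their synonyms alone, and the lists were also tested without them.

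The tests were tested on simulated data. With 50% of 3000 simulated peaks shared, 50.2% were matched, and 1 of 40 unrelated pairs of lists passed. Of 20 simulated lists with 18 of 30 members bound, 20 were found, and 1 of 200 null lists was called. A motif planted in 4% of 3000 windows was recovered in full, and 0 of 17 motifs were called without planting. The simulated summit and control windows had the same base composition, so these counts do not cover calls that a composition difference could give. Alternatives varied the matching distance, the TSS window, the peak set, the background and the build, and left out each replicate in turn by using the strongest 3607 peaks of the other.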

Results

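Chromatin immunoprecipitation followed by sequencing was used to map the genomic sites of Hr96 in whole adult female Drosophila melanogaster. Hr96 (also called DHR96) is a nuclear receptor known for roles in sterol and triacylglycerol metabolism and in the response to foreign compounds. The flies carried a transgene for Hr96 fused to a green fluorescent protein, and the fusion was precipitated with an antibody to that tag. Neither of the 2 samples lacks the fusion, so signal unrelated to Hr96 could not be told apart from Hr96 binding. Below, an Hr96 site or a bound gene means one with a peak in this precipitation. The 2 samples are biological replicates 1 and 3 of 1 group, with no second condition, so the comparisons are between the replicates, between positions in the genome, and between groups of genes. Each replicate has a list of 30000 peaks and background regions on the dm6 build, another list of 30000 comes from the pooled replicates, and 3607 peaks make up the final list chosen by the irreproducible discovery rate (IDR). Every IDR peak was among the 3607 strongest of the pooled list. Read totals are not given in the sources used here, so the sequencing depth behind each peak is unknown.

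The strongest Hr96 sites recurred in both replicates, and the weaker ones did so less often. Of the 100 strongest peaks of replicate 1, 98% had a summit within 100 bp of one of the 3607 strongest summits of replicate 3. That share was 27.2% for the peaks ranked 2001 to 3607. Over all 3607 strongest peaks, 1840 (51.01%) were matched, against a mean of 0.543% after circular shifts along each chromosome arm (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). Of the IDR peaks, 80.1% had a matching peak in the lists of both replicates, and 41 matched neither. Across 2888 matched IDR peaks the log2 signals of the replicates had a Spearman rho of 0.563 and a Pearson r of 0.658, a correlation across peaks, which are not independent replicates. Replicate 1 had the higher signal, by a median of 0.90 on the log2 scale (SD 0.84 across peaks), on a scale that the peak caller set separately for each library. Both replicates were called against 1 shared control file, which can add to the overlap.

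**Figure D1:**
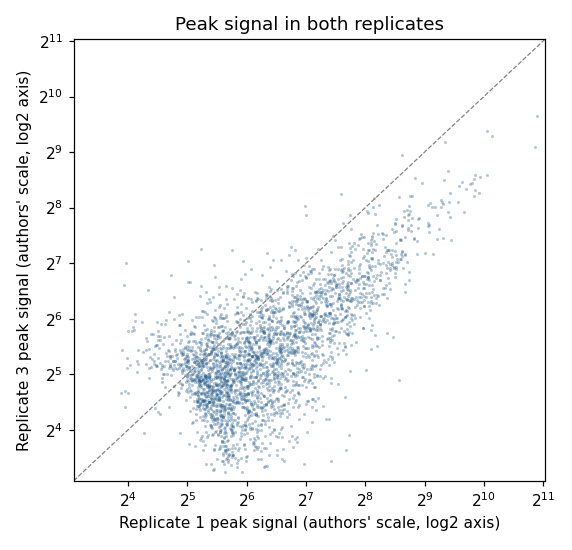
Peak signal in replicate 1 (x axis) and replicate 3 (y axis), both on log2 axes in the authors' units, for the 2888 IDR peaks with a summit within 100 bp in both lists, 1 point per peak; the dashed line marks equal signal. Points spread along the diagonal with a Spearman rho of 0.563 and lie mostly below it.

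No peak lay in the Hr96 gene itself. Hr96 (FBgn0015240, dm6 chromosome 3R, 25025235 to 25029351) had no summit inside the gene in the IDR list, the pooled list or either replicate's list. The nearest pooled summit was 19432 bp from its transcription start site (TSS), and the nearest in replicate 3 was 15329 bp away. A pair of genes known to respond to Hr96 had no peak at the promoter. Neither mag (magro, FBgn0036996, chromosome 3L), a gut lipase and sterol esterase, nor Npc1b (FBgn0261675, chromosome X), which takes up dietary sterol in the gut, had a peak within 500 bp of a TSS in the pooled list or in either replicate. The pooled summit nearest to the mag TSS was 1533 bp away and ranked 13133, inside the gene, as was 1 summit of replicate 3 (1485 bp from the TSS, rank 4590) and none of replicate 1, and that nearest to the Npc1b TSS was 18417 bp away.

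The strongest peak of all lay at the promoter of Ugalt, which encodes a transporter of UDP-galactose into the Golgi. It spans 2703694 to 2704086 on the X chromosome, 27 bp from the TSS, with a signal of 2692, and it ranked 1 in both replicates (signals of 1914 and 801.3 in replicates 1 and 3). The next was at the promoter of CG14100 on chromosome 3L (19590421 to 19590810, signal 2412). The third lay in an intron of Tlk, the Tousled-like kinase of chromatin assembly, on the X (3742050 to 3742413, signal 1758, 2334 bp from the nearest TSS). Introns also held the peaks of CG11050 (chromosome 2L, 6612465 to 6612903, signal 1723) and CG32772 (X, 4910189 to 4910575, signal 1346). A further intronic peak, in CG32486 on chromosome 3L (3060626 to 3060961, signal 1288), was nearest to CG16753, whose TSS was 5700 bp away. The other 4 of the 10 strongest were at promoters on chromosome 2R. They belonged to mRpL41, a protein of the mitochondrial ribosome (15217578 to 15217929, signal 1450), Sox14, a transcription factor of the ecdysone response (23978375 to 23978760, signal 1297), eIF6, a factor of large ribosomal subunit formation (23850246 to 23850566, signal 1272), and Pal1, an enzyme of peptide amidation (9959708 to 9960099, signal 1245). All 10 ranked within the top 10 of replicate 1 and the top 21 of replicate 3. The eIF6 summit, 105 bp from the TSS of eIF6, also lay inside the gene ytr.

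Hr96 sites concentrated at promoters. Of 3607 IDR summits, 2325 (64.5%, exact 95% confidence interval 62.9 to 66.0%) lay within 500 bp of an annotated TSS, 4.74 times the 13.6% of random positions matched for chromosome arm (one-sided permutation p = 0.0001, the smallest that 10000 random sets can give). The 15000 weakest peaks of the pooled list had 12.97% at promoters, an odds ratio of 12.2 between the lists by Fisher's exact test. Coding exons held 12 IDR summits (0.333%, against 13.1% at random), 3' untranslated regions 0.832% (5.04% at random), introns 25.6% (39.4% at random) and intergenic sequence 7.15% (27.3% at random), each below random with a permutation p of 0.0001 over the random sets. The 5' untranslated regions outside the promoter windows (0.887%, p = 0.25) and other exons (0.776%, p = 0.45) were not distinguishable, by the same permutation test, from random positions, although without replicate 1 the 5' untranslated regions were above random (1.08%, unadjusted permutation p = 0.03). The promoter share was 73.8% in the strongest 722 IDR peaks and 54.6% in the weakest 721. The median distance from a summit to the nearest TSS was 213 bp.

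**Figure D2:**
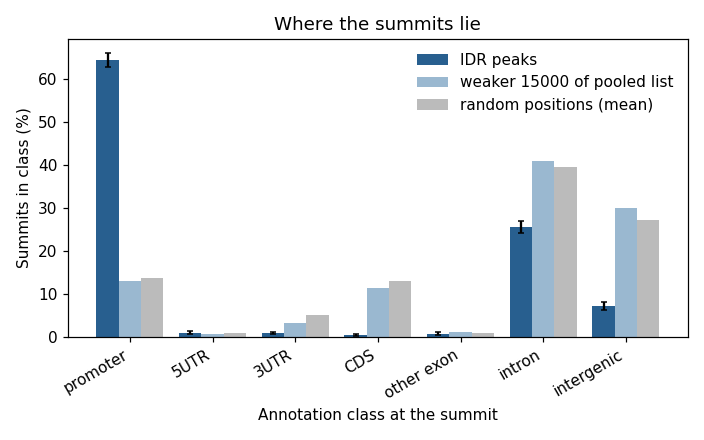
Share of summits (y axis, %) in each annotation class (x axis) for the 3607 IDR peaks with exact 95% confidence intervals, the 15000 weakest peaks of the pooled list, and the mean of random positions matched for chromosome arm. Promoters (within 500 bp of a TSS) hold 64.5% of the IDR summits and 13.6% of the random positions.

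Chromosome 4, the small and largely heterochromatic chromosome, was nearly free of peaks, and the call for the X chromosome changed with the peak set. Chromosome 4 had 5 IDR peaks, 0.139% of the list (exact 95% interval 0.0450 to 0.323%) against 1.01% of arm length (exact binomial test, adjusted p = 1.1e-09 over 6 arms). With only the strongest peaks of replicate 3, that is without replicate 1, its share was 0.444%. The X had 620 peaks, or 17.2% against 17.6% of length (exact binomial test, adjusted p = 0.67). That direction turned among the 1803 strongest IDR peaks, where the X held 19.5% (unadjusted exact p = 0.033), and without replicate 1, where it held 19.2% (p = 0.011). In a split by rank chosen after seeing the data, the X held 22.1% of the 1000 strongest IDR peaks (exact 95% interval 19.6 to 24.8%). At ranks 1001 to 3607 it held 15.3% (13.9 to 16.7%), so the 17.2% averages over departures in both directions. On dm3 the X was below its share, with 16.6% (unadjusted exact p = 0.0015, against arm lengths approximated by the furthest peak). Arms 2L, 2R, 3L and 3R held 18.1%, 19.1%, 20.3% and 25.1% of the peaks, with adjusted exact p from 0.29 to 0.70. The Y, which females lack, had no IDR peak, and 4 peaks in each list of 30000.

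Genes of cytosolic ribosomal proteins were the most often bound group. Of 85 measured members, 60 (70.6%, exact 95% interval 59.7 to 80.0%) had an IDR summit within 500 bp of a TSS, against 17.8% of other protein-coding genes (Fisher's exact test, adjusted p = 4.9e-25 over 16 lists). RpL32 (signal 806.7, rank 39), RpS27 (707.5, rank 50), RpS28b (629.8, rank 65) and RpL34b (555.7, rank 83) had the strongest peaks of the list, and they ranked 28 to 75 in replicate 1 and 101 to 167 in replicate 3. Over the genome, 2526 of 13945 protein-coding genes (18.1%) had a summit within 500 bp, and 598 peaks were the strongest for more than 1 gene, so neighbouring genes can share a call. Genes with more TSSs had more chances of a call. No list or family here or below was matched to the background for TSS number or expression, so a difference in share need not be particular to Hr96.

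Genes of triacylglycerol metabolism, one of the processes Hr96 is known for, were also bound more often than other genes. The count was 14 of 27 (51.9%, exact 95% interval 31.9 to 71.3%, Fisher's exact test, adjusted p = 0.00059). By rotation of gene labels, which keeps neighbouring genes together, the adjusted p was 0.0048. Lpin, the phosphatidate phosphatase that makes diacylglycerol, had the strongest peak (signal 408.8, rank 184; 272.5 in replicate 1 and 136.1 in replicate 3). FASN1, the fatty acid synthase (signal 141.5), Gpat4, a glycerol-3-phosphate acyltransferase (134.9), and Desat1, a fatty acid desaturase (134.1), came next, and the lipase gene bmm ranked 1622. Most of these peaks were of middle strength, and the call was lost among the 1803 strongest IDR peaks (29.6% bound, adjusted p = 0.063, Fisher's exact test), where 1571 genes were bound in all, against 2526 in the full list. It was also lost among the IDR peaks matched in the 3607 strongest of both replicates, a set chosen after seeing the data (22.2%, adjusted exact p = 0.21, with 1540 genes bound in all). Gpat4 was not bound among the strongest peaks of replicate 3. ACC, ATPCL and CG5966 had no matching peak in the list of replicate 1, and Fatp1 and Hsl had none in that of replicate 3. Apoltp in replicate 3 (rank 3800) and Agpat3 in replicate 1 (rank 4274) also fell outside the 3607 strongest. The other bound genes of the list had a matching peak within the 3607 strongest of both replicates.

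Testis genes, a control group for female flies, were bound at 0 of 36 members, which allows a share of up to 8.33% (Fisher's exact test, adjusted p = 0.0085, and 0.043 by rotation of gene labels, which keeps neighbouring genes together). That call too was lost among the 1803 strongest IDR peaks (0 bound, adjusted exact p = 0.12), where fewer genes were bound in all.

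Sterol and detoxification genes, the other groups Hr96 is known for, were not detectably bound more often than other genes. Chromatin came from whole females, so binding limited to a single tissue was not tested. Sterol-handling genes counted 4 of 24 (16.7%, exact interval 4.74 to 37.4%, Fisher's exact test, adjusted p = 1). That interval reaches well above the 18.1% of other genes, so a higher share was not excluded. The bound members were Abca3 (signal 151.0), the fatty acid transporter gene Fatp1 (105.2) and the lipoprotein receptor genes mgl (94.3) and LpR2 (91.0). Xenobiotic genes counted 4 of 53 (7.55%, adjusted p = 0.13 by the same exact test), and they passed the threshold as a depleted group when gene bodies were counted (adjusted p = 0.024). Their strongest peaks were at cnc (signal 194.2) and Keap1 (169.2), the regulators of the oxidative stress response, with GstD1 (99.9) and Cyp28a5 (64.4) below them. Of the nuclear receptor genes, with Hr96 itself counted as unbound, 6 of 21 were bound (28.6%, adjusted exact p = 0.43), with the strongest peaks at ERR (signal 328.7), Eip75B (292.9) and usp (289.9). The ERR summit lay inside the gene Atg18a, and the usp summit inside both usp and Actn.

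No other fixed list passed Fisher's exact test after adjustment. Nutrient signalling genes counted 10 of 31 (adjusted exact p = 0.13), led by REPTOR, a transcription factor downstream of TORC1 (signal 522.3, rank 97), the insulin receptor gene InR (294.1), and Thor, the 4E-binding protein (214.9). Circadian genes counted 6 of 13 (adjusted exact p = 0.075), led by sgg (347.6) and cry (327.9), and they passed without replicate 1 (53.8%, adjusted p = 0.014). Heat shock and chaperone genes counted 8 of 22 (adjusted exact p = 0.13), led by Hsp83 (547.5) and Hsp27 (543.3), and they passed without replicate 1 as well (45.5%, adjusted p = 0.013). Oogenesis genes counted 9 of 43 (adjusted exact p = 0.79), among them plu (190.8, a peak that is also counted for the ribosomal protein gene RpS18), nanos (167.8) and Sxl (139.7), and proteasome genes 4 of 38 (adjusted p = 0.43), led by Rpn5 (336.4). The marker lists of single tissues counted 2 of 20 for neurons (elav, 688.9, and Syx1A, 71.1), 3 of 18 for muscle (Zasp52, sls and Mef2), 2 of 26 for gut (GATAe and Vha16-1) and 1 of 16 for fat body (FASN1), against 18.1% of all protein-coding genes. Their adjusted exact p were 0.69, 1, 0.42 and 0.45. The control list for Polycomb-repressed loci counted 2 of 24, at the homeobox gene Dll and at hb, which is not a homeobox gene (adjusted exact p = 0.43). The summits counted for nanos, Rpn5 and elav lay inside the genes CG11779, Hat1 and arg, in that order.

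**Figure D3:**
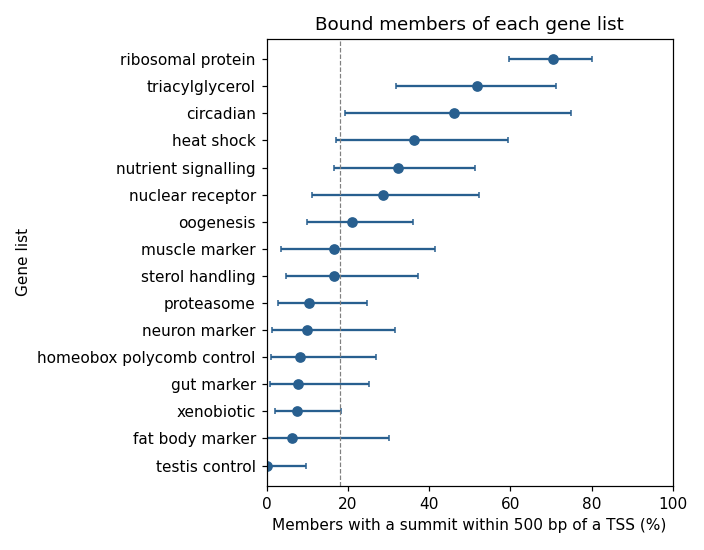
Percent of the members of each fixed gene list (y axis) with an IDR summit within 500 bp of a TSS (x axis, %), with exact 95% confidence intervals; the dashed line marks the 18.1% of all protein-coding genes. Ribosomal protein genes reach 70.6% and triacylglycerol genes 51.9%, and no testis gene is bound.

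The sequence under the summits held motifs of promoter and insulator factors, and fewer nuclear receptor core motifs than the flanks. GC content was 40.2% in summit windows and 43.3% in flank windows, and the flanks were not matched for it. AGGTCA, the core sequence of nuclear receptor sites, occurred within 100 bp of 3.52% of summits (exact 95% interval 2.94 to 4.18%) and in 5.32% of flanking windows 1000 bp away, a ratio of 0.661 (exact sign test, adjusted p = 0.00041 over 17 motifs). That call was lost within 50 bp of the summits (ratio 0.711, adjusted exact p = 0.084) and among the 1282 IDR peaks over 500 bp from any TSS (0.841, adjusted p = 0.75). DRE, the promoter element bound by DREF, was in 4.46% of summit windows and 0.610% of flanks (ratio 7.32, adjusted exact p = 4.5e-26). The M1BP promoter motif was in 1.94% and 0.305% (ratio 6.36, adjusted p = 5.0e-11), and the insulator motif of CTCF in 2.97% and 0.582% (ratio 5.10, adjusted p = 1.4e-14), all by the same exact test. Without replicate 1 these ratios were 4.03, 3.62 and 2.47, and each still passed. The pattern listed as an Ohler core promoter motif (KTATCGMT, with K for G or T and M for A or C) had a ratio of 2.55. The BEAF motif had 4.25 (17 summits against 4 flanks). Both patterns share bases with the DRE sequence TATCGATA, so they are not independent of it. GAGA (ratio 1.49) and the forkhead motif (1.51) passed as well, but so did AGTGCA, a scrambled control (1.40, adjusted exact p = 4.5e-08), and the differences from that control were not tested. AGTGCA has the bases of AGGTCA in another order. Whether Hr96 binds AGTGCA was not tested, so its excess need not be background. The extended core motif (0.667), the DR1 and inverted repeats (4 and 1 summits), E-box (0.868), GATA (1.04), Zelda (0.711) and the other scrambled control (1.08) did not pass, and the DR4 repeat had no match. Among those 1282 peaks away from any TSS, CTCF stayed at a ratio of 6.88, while DRE fell to 1.38 (adjusted exact p = 1) and M1BP had no summit match. Among the strongest 361 IDR peaks, a set chosen after seeing the data, DRE alone passed (17 summits against 1 flank, adjusted exact p = 0.0025), and M1BP (3 against 2), KTATCGMT (10 against 9) and CTCF (10 against 2, adjusted p = 0.18) did not.

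**Figure D4:**
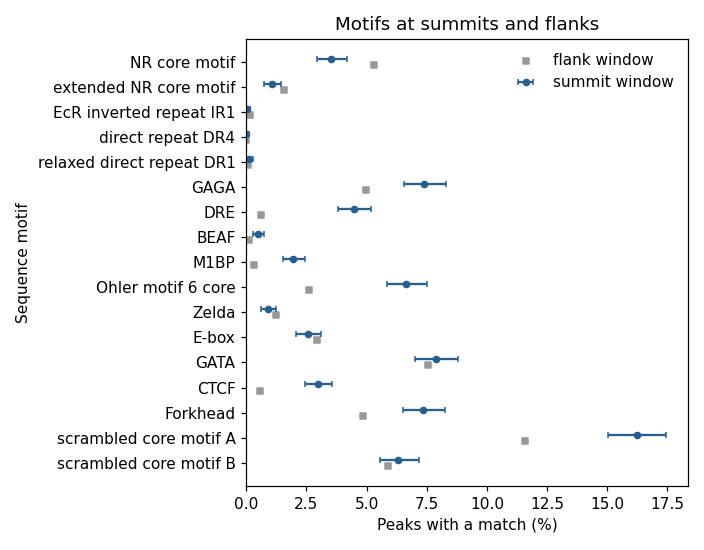
Percent of the 3607 IDR peaks with each motif (y axis) in the window reaching 100 bp to each side of the summit, with exact 95% confidence intervals, and in 1 flanking window per peak centred 1000 bp away (x axis, %). DRE stands at 4.46% of summits and 0.610% of flanks, and the nuclear receptor core motif at 3.52% and 5.32%.

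The same libraries processed on the older dm3 build gave 3534 IDR peaks, against 3607 on dm6. Their median signal was 96.5, against 102.6 on dm6. The dm3 list put 648 peaks on 2L, 677 on 2R, 715 on 3L, 896 on 3R, 4 on chromosome 4 and 584 on the X, and the dm6 list 654, 690, 731, 907, 5 and 620. The dm3 IDR list held 10 peaks on sequences outside the 6 main arms, and the dm6 IDR list held 0.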

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

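The comparison of the replicate lists with the pooled list was chosen after the lists had been seen, and so were the tests of the X chromosome share of the strongest peaks, of the core motif in the strongest 361 peaks, of the gap length around Hr96, and the comparison of DRE with the scrambled control.

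A signal outside the pooled and IDR lists, which the comparisons by position and by gene rest on, was found in 29 places. These 29 peaks were among the 3607 strongest of both replicates, with matching summits, and so count in the replicate overlap, but no peak of the pooled list lay within 500 bp, and for 21 of them none lay within 2000 bp. Of the 29, 14 were among the 1000 strongest of replicate 1, such as those at the promoters of pre-mod(mdg4)-E (signal 371.9 in replicate 1 and 144.2 in replicate 3) and dpa, a replicative helicase subunit (245.1 and 124.2). The dm3 lists held 38 such peaks.

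Weak peaks were rare on the X chromosome. The X held 7.63% of the 15000 weakest pooled peaks (exact 95% interval 7.21 to 8.07%) and 17.6% of arm length, with 7.97% and 10.4% at those ranks in replicates 1 and 3. GC content argues against itself as the cause, since the autosomal rates of weak peaks by GC content predict an X share of 17.4%, and repeats do as well, since the X makes up 17.4% of unmasked sequence. Fewer X reads in the precipitated libraries than in the control could lower the share, and the 22.1% share of the X among the 1000 strongest peaks cannot decide, because strong sites can be more frequent on the X for other reasons and coverage was not used here. No biological explanation was tested, as the design has 1 group.

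Summits held promoter motifs and few nuclear receptor core motifs. Sequence composition remains open for the difference between bound and unbound promoters. DRE was more frequent at bound than at unbound promoters (odds ratio 1.42, 95% interval 1.23 to 1.63, Fisher's exact test), which met the bound set beforehand, an interval above 1. The scrambled control AGTGCA met it too (1.20, interval 1.09 to 1.32), and so did the E-box (1.35), so that bound does not tell a difference particular to DRE from one shared with other sequences. In the same comparison GAGA lay above the interval of AGTGCA (1.78, interval 1.54 to 2.05), the other scrambled control, with the same bases as AGTGCA, did not differ (0.951, adjusted exact p = 0.53), and the core motif was less frequent at bound promoters (0.761, interval 0.651 to 0.887). Within 50 bp of the summits, the DRE sequence TATCGATA was in 95 windows, against 7 after a shuffle that keeps dinucleotide counts. That difference (Fisher's exact test, adjusted p = 1.4e-17 over 11990 words) argues against dinucleotide content as the source of DRE at summits. It does not bear on the difference between bound and unbound promoters, and the word test was chosen after the data had been seen. A signal at every strongly transcribed locus is argued against by tRNA genes, of which 4.14% had a summit within 500 bp against 18.1% of protein-coding genes, but tRNA genes are near-identical copies with another polymerase, and strongly transcribed genes of the ribosomal kind remain open because no expression values were used here. An excess of the core motif in the strongest peaks is argued against by its 2.77% share at the summits of the strongest 361 peaks (exact 95% interval 1.34 to 5.04%), against 6.09% of their flanks (22 flanks, exact sign test p = 0.043, and 0.18 after adjustment, so the deficit itself does not pass there), and by its ratio of 0.606 in the 1803 strongest (adjusted exact p = 0.0057). No biological explanation was tested here either.

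No peak of any list lay in Hr96, and the nearest, in replicate 3, had its summit 15329 bp outside the gene. The pooled list has a gap of 68960 bp there (3R, 25005803 to 25074763), and repeats are argued against by its 8.60% of masked bases, below the median of 15.8% for stretches of that length on 3R. Chance remains open: 4.64% of protein-coding gene starts lie in as long a gap of the pooled list. That is under the 5% bound for that list, which was set after the lists had been seen but before this value was. The lists of replicates 1 and 3, added after that value was seen, gave 5.78% and 4.79%, on both sides of the bound. Extra copies of the locus from the transgene were not tested.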

How the results depend on the processing

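The sets of IDR peaks matched in both replicates, the opposite flanks and the lists without hand-resolved names were chosen after the data had been seen; all other alternatives were planned. Replicate overlap ran from 38.5% to 58.3% and the promoter share from 48.2% to 74.8%, and both stayed above their null in every alternative. The ribosomal protein list passed in each alternative, with 60% to 74.1% bound. The Spearman rho moved to 0.614 with summits within 50 bp, where fewer peaks match. The X share rose above its length in the 1803 strongest IDR peaks (19.5%), ranged from 16.9% to 19.2% when 1 replicate was left out, and fell below it on dm3 (16.6%, exact p = 0.0015, with approximate arm lengths); the cause was not tested. Against 3 lists passing, there was 1 among the 1803 strongest peaks and 1 among the IDR peaks matched in both replicates, where fewer genes are bound (1571 and 1540, against 2526), and triacylglycerol genes stood at 29.6% and 22.2% and testis genes at 0 in both. Counts ranged from 3 to 5 lists when 1 replicate was left out, and gene bodies gave 5, with xenobiotic genes depleted at 7.55%. The unresolved names left the same number passing, 3. Motifs passing were 9, with the depleted core motif and 1 scrambled control among them, and 4, that control included, in the peaks over 500 bp from any TSS, where the nuclear receptor core motif had a ratio of 0.841, DRE 1.38, M1BP 0 and BEAF 0.333, in fewer peaks. In windows of 50 bp the core motif had a ratio of 0.711 and GAGA 1.20, and GAGA had 1.34 in the 1803 strongest, none of the 3 passing. Opposite flanks gave 0.686 for the core motif, which passed. Of 49 named list genes, 37 were bound in the 1803 strongest peaks, 42 without replicate 1, 46 without replicate 3 and 34 with a 200 bp window.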

Other observations

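The gene families, the sequence words and the comparison of peak strength were chosen after the data had been seen.

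Beyond cytosolic ribosomal proteins, several families of genes that all cells use were bound more often than other genes, and families of sensory and cuticle genes had no bound member in the IDR list. Mitochondrial ribosomal protein genes counted 21 of 73 (28.8%, Fisher's exact test, adjusted p = 0.044 over 15 families), led by mRpL41, mRpS23 (signal 902.9) and mRpL23 (671.7), and they also passed without replicate 1 (adjusted p = 0.0045) and without replicate 3 (0.028). Vacuolar ATPase subunit genes, which acidify organelles, counted 12 of 33 (adjusted p = 0.032), translation elongation factors 4 of 7 (adjusted p = 0.044) and ubiquitin-conjugating enzymes 5 of 9 (adjusted p = 0.032, Fisher's exact test). The vacuolar ATPase call was lost without replicate 1 (adjusted exact p = 0.15) and without replicate 3 (0.088), and those of the elongation factors and conjugating enzymes without replicate 1 (0.054 and 0.11). Cuticular protein genes counted 0 of 70, odorant receptors 0 of 59 and gustatory receptors 0 of 60, which allows up to 4.29%, 5.08% and 5% (Fisher's exact test, adjusted p = 1.8e-05, 5.6e-05 and 5.6e-05), and all 3 passed without either replicate, with 1 odorant receptor, Or49b, bound without replicate 1. Cytochrome P450 genes, many of which oxidise foreign compounds, counted 6 of 85 (7.06%, adjusted exact p = 0.025), led by Cyp6u1 (signal 286.2), and this call was lost without replicate 3 (adjusted p = 0.10). Fisher's test treats neighbouring genes as independent. Rotation of gene labels, which keeps neighbours together, gave weaker adjusted p: 0.0045 for each of the cuticular, odorant and gustatory families and 0.046 for cytochrome P450 genes. Complex I subunits (6 of 40), ATP synthase subunits (2 of 15), initiation factors (10 of 44), aminoacyl tRNA synthetases (6 of 18), spliceosomal proteins (4 of 11), Jonah proteases (1 of 16) and histone variants (1 of 5) did not pass, although the synthetases passed without replicate 1 (8 of 18, adjusted exact p = 0.025).

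Ribosomal protein promoters also had stronger peaks. The median signal was 265.8 at the 60 bound ribosomal protein genes and 124.0 at the other 2466 bound genes, 2.14 times as high (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give).

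Among 8-base words within 50 bp of the summits, ATCGATAG, which holds part of the DRE, had the lowest p against shuffled sequence, in 94 windows against 5 (Fisher's exact test, adjusted p = 8.2e-19 over 11990 words). CAACACTG, which is in none of the fixed motifs, was in 91 windows against 9 (adjusted exact p = 4.2e-15). In the 1282 peaks over 500 bp from any TSS, GATGGCGC, part of the CTCF motif, had the lowest p, with 28 windows against 0 (adjusted exact p = 7.0e-06), followed by CACAGTGG with 29 against 1 (adjusted p = 2.7e-05).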
